A study of Bos taurus with 10 samples.

How the data were processed

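The samples were intramuscular and subcutaneous adipose tissue of cattle (Bos taurus) from 5 heifers, 5 libraries per depot, each library assigned to its depot and replicate number by its title in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and a column kit, fragmented, copied with random hexamers, given a dUTP-marked second strand and sequenced in pairs on an Illumina instrument after 10 cycles of PCR. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.11a, featureCounts 2.0.2 and DESeq2 1.42.0. The genome build and the strand setting of the counting are not given in the sources used here, so the coordinates printed are those of the deposited table, and reads of overlapping genes on opposite strands, or shared by near-identical gene copies, cannot be told apart.

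The authors deposited a table of 12674 genes with raw counts per gene and library, which are whole numbers that sum to a different total in each library. It also holds the authors' mean of raw counts per depot (an authors' value in no standard unit), a DESeq2 base mean (a signal scaled by size factors, as the deposited values show), a deposited log2 fold change, and a deposited p-value and adjusted p-value. The deposited adjusted p-value equals a Benjamini-Hochberg adjustment over exactly the 12674 listed genes in 100% of genes (tolerance 1%), and size factors from these genes give the deposited base mean in 100% (tolerance 0.1%), so the authors' test used the genes listed. Totals are therefore totals of listed genes, not of sequenced reads: 9392739 to 14836808 in intramuscular and 13776094 to 17685678 in subcutaneous fat. Genes are named by symbol. For 18 genes whose symbols had been turned into dates, and 1 without a symbol, the Ensembl identifier stood in. No gene of the myofibre list (32 genes) or of the mitochondrial genome list had values, so results that needed them were not analysed here. All CPM values below were computed from these counts with edgeR's scaled library sizes.

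The main test was edgeR 4.0.16's quasi-likelihood test (two-sided, TMM scaling, filterByExpr on depot, no block) with Benjamini-Hochberg adjustment at 0.05, run in R 4.3.3, which kept 12521 genes and removed 153. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, lists with at least 4 tested genes, 31 of 37 lists), and with fry and camera with an estimated correlation as alternatives. None of the 31 lists passed with an estimated correlation, while fry, which asks only whether a list's genes move one way on balance, called 6. The 37 lists, the designs, the alternative settings and the rule for named genes were fixed before the data were examined. The residual muscle list, 3 other lists and the alternatives built on the residual muscle share were chosen after seeing the data. The list p-values of these 4 added lists were adjusted over the 4 alone, apart from the 31. Both steps were tested on simulated counts with known changes. Of 12371 genes simulated for this comparison 198 were changed. Of those changed 2-fold 43.0% were called, and of those changed 4-fold 84.7%. Of the calls 2.33% were unchanged genes, and 1.50% of unchanged lists had a p under 0.05. The data gave 1533 calls, far more than the genes changed in the simulation, so the shares called need not carry over. The simulated genes varied independently and without an animal effect. The lists called here had estimated correlations of up to 0.56, so the simulated rate for lists does not carry over to them.

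Named genes were the 8 largest rises and 8 largest falls among genes past the threshold with a symbol, a mean of at least 1 CPM and no overlap between depots, the 5 smallest p in each direction, 16 fixed fat genes, up to 4 genes of smallest p in each list and up to 3 called genes that went against a list's median. The rule names 160 genes with values, of which 83 appear in the text, and 1 other is withheld and not reported here. The 83 were picked from them after their values with each library left out had been seen, and genes that lost their call that way were mostly passed over. Of the called genes, 65 of 72 in the text but 3 of 30 of the others kept the call in all 10 such fits. The share that describes the rule is 68 of 102. C2, C3, MASP1, THBS4, FMOD, TNMD and ENSBTAG00000052709 were chosen after their values were seen. So was CIDEA, which the statements on alternative settings do not cover. Log2 CPM used a prior count of 2. Where every subcutaneous library was at 0, a fold is a lower bound against 3 counts over the 5 subcutaneous libraries (0.0390 CPM), which covers counting error only.

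Replicate numbers were taken as pairs. The design text says that both depots came from the same 5 heifers. The deviations of same-numbered libraries from their depot means correlated across genes at 0.102, 0.181, 0.176, 0.161 and 0.237, and 10 of 10 libraries correlated best with their own number. Genes are not independent replicates in these values. Replicates of a depot differed by more than sampling noise in all 20 pairs (chi-square per degree of freedom from 24.4 to 171), so none was counted as a repeat. Alternatives were edgeR's RLE scaling, no filter, a stricter filter (1 CPM in 5 libraries), the animal as a block, each library left out, DESeq2 1.42.0, and limma voom with quality weights.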

Results

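RNA was sequenced from 2 fat depots of 5 adult Angus-cross heifers, the fat that lies between muscle fibres (intramuscular fat, marbling) and the fat under the skin (subcutaneous fat). The purpose named for the series was to find what may make marbling fat accumulate later and more slowly. Each depot gave 5 libraries, numbered 1 to 5, and the same number in both depots was taken as the same animal. The deposited table lists 12674 genes. The counts over these genes were 9392739, 12559961, 12639503, 14579575 and 14836808 in intramuscular replicates 1 to 5, and 15720452, 13776094, 17685678, 17334997 and 17317309 in subcutaneous replicates 1 to 5. The first principal component held 46.1% of the variance and separated the depots.

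**Figure D1:**
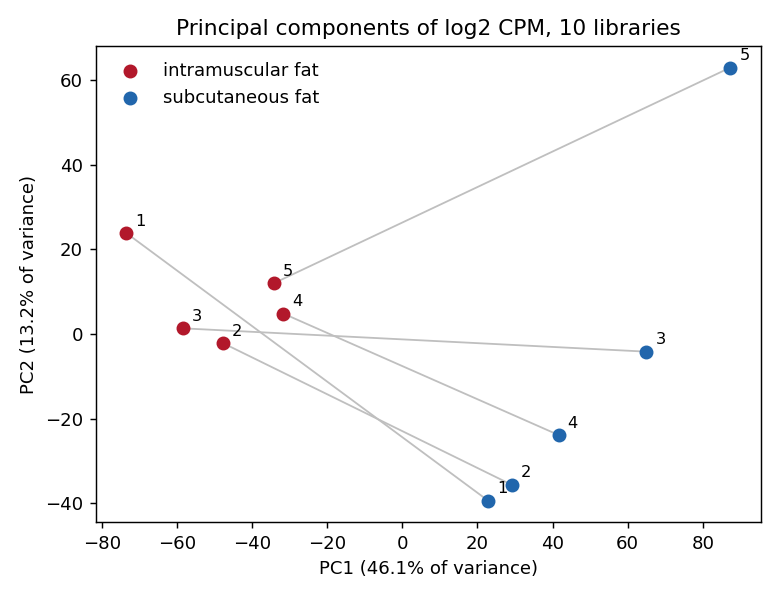
Principal components of log2 CPM in the 10 libraries, with the first component (46.1% of the variance) on the x axis and the second (13.2%) on the y axis. Each point is a library with its replicate number, red for intramuscular and blue for subcutaneous fat, and grey lines join libraries with the same number. All 5 intramuscular libraries lie below 0 on the first component and all 5 subcutaneous libraries above it.

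In intramuscular fat, transcripts of striated muscle and of nerve were among the largest rises, and the sulfotransferase gene CHST9, complement factor CFB and the patterning gene IRX5 had the largest falls under the rule for named genes. NMRK2, a nicotinamide riboside kinase of striated muscle (ENSBTAG00000031573, chromosome 7, 20064778 to 20069191), reached 160.4 ± 64.5 CPM (SD, n = 5). It had no count in any subcutaneous library and was at least 4115-fold higher (floor of 3 counts over the 5 subcutaneous libraries). ANO5, CACNG6, LRRC30, NEFM and CACNA2D2 also had no subcutaneous count and were at least 513-, 412-, 402-, 329- and 323-fold higher. Without intramuscular replicate 1 the bounds were 234-fold for CACNG6 and 185-fold for CACNA2D2. NEFM encodes a neurofilament of axons, and CACNG6 and CACNA2D2 encode calcium channel subunits. SYNPO2L, a Z-disc protein, and GADL1, an amino acid decarboxylase, measured 145 ± 126 against 0.0528 ± 0.0731 CPM and 83.4 ± 69.9 against 0.0470 ± 0.105 CPM (mean ± SD, n = 5). Without intramuscular replicate 1 their intramuscular means were 93.3 and 53.9 CPM. Their subcutaneous means rest on 4 counts each, and were 0.0294 CPM for SYNPO2L without replicate 2 and 0 for GADL1 without replicate 4. The rises with the smallest p also included CPE, a carboxypeptidase that processes prohormones (ENSBTAG00000016514, chromosome 17, 573369 to 721435), at 184 ± 39.3 against 25.1 ± 5.40 CPM, the kinase MAPK4 (34.0 ± 11.5 against 0.398 ± 0.250 CPM) and the actin-severing protein DSTN (968 ± 214 against 156 ± 19.7 CPM). Their log2 fold changes were 2.88 ± 0.20, 6.40 ± 0.45 and 2.63 ± 0.19 (± SE), with adjusted p of 1.43e-05, 1.43e-05 and 1.6e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

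Among the genes lower in intramuscular fat, CHST9 fell by 4.41 on the log2 scale and was counted in 1 of the 5 intramuscular libraries, replicate 4, without which its intramuscular mean was 0. CFB fell from 332 ± 191 CPM in subcutaneous to 44.1 ± 48.4 CPM in intramuscular fat (22.7 CPM without intramuscular replicate 2). IRX5, the radial spoke gene RSPH14, the zinc finger gene ZBTB32, the transporter gene SLC4A11, the microRNA gene bta-mir-2443 and the anion channel gene LRRC8E had log2 fold changes of -2.87, -2.59, -2.58, -2.56, -2.51 and -2.50. Their edgeR adjusted p lay between 0.00131 and 0.0215. Several of these falls were at low levels. CHST9, RSPH14, ZBTB32, bta-mir-2443 and LRRC8E measured 0.0949, 0.529, 0.324, 0.593 and 1.02 CPM in intramuscular fat. In subcutaneous fat these genes measured 2.32, 3.22, 2.02, 3.47 and 5.89 CPM. The falls with the smallest p were those of the sulfotransferase gene CHST1 (ENSBTAG00000003721, chromosome 15, 75702165 to 75705849; 25.5 ± 4.30 against 59.2 ± 6.56 CPM), TMEM158, the phosphatase gene PPM1F, the adhesion gene SDK1 and the actin-bundling gene ESPN. Their log2 fold changes were -1.22, -1.67, -1.04, -1.04 and -1.61. These 5 genes had edgeR adjusted p between 0.000544 and 0.00121. ZBTB32 passed the threshold in all fits that left out 1 library except those without intramuscular replicate 2 (adjusted p = 0.0518) and replicate 5 (0.0501).

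Of 12521 genes tested, 845 were higher and 688 lower in intramuscular fat at an adjusted p of 0.05, and 603 and 252 of these differed by at least 2-fold. This test did not pair the depots by animal. With the animal as a block 1013 genes were higher and 871 lower, and 1385 of the calls were shared. The 5 values of one depot lay entirely above those of the other for 1614 genes (12.9% of those tested, against 0.794% by chance). The authors' deposited table, from DESeq2, lists 1365 genes higher and 1171 lower at an adjusted p of 0.05, and all 1533 genes called here are among them with the same direction. The lower calls numbered 369, 373, 263, 445 and 361 without intramuscular replicate 1, 2, 3 or 5 or subcutaneous replicate 3 in turn. The higher calls numbered 494 without intramuscular replicate 3, and the lower calls of at least 2-fold 158 and 151 without intramuscular replicates 1 and 3. Without the 2 libraries richest in residual muscle transcripts, intramuscular replicates 1 and 3, 306 genes were higher and 67 lower (289 and 51 by at least 2-fold).

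Muscle fibre transcripts were measured through 27 striated muscle genes with values, a list chosen after the data were seen and referred to as the residual muscle list. None of the 32 myofibre genes had values, so the share of this list is a partial index and not the muscle share of the RNA. The list took 0.243 ± 0.204% of counts in intramuscular fat and 0.0167 ± 0.00260% in subcutaneous fat (SD, n = 5). The geometric means of the shares differed 11.4-fold. The share was higher in all 5 pairs (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 libraries allow). By pairs, the two-sided exact sign-flip permutation p was 0.0625, the smallest that 5 pairs allow. The intramuscular libraries differed widely, at 0.584, 0.153, 0.281, 0.0924 and 0.106% in replicates 1 to 5. On the first principal component they lay at -73.6, -47.8, -58.4, -31.7 and -34.2. This is the order of their shares, so that component also followed the residual muscle share within the depot. Of the 27 genes, 17 were higher and 0 lower in intramuscular fat (24 and 0 when adjusted over the list alone), with a median log2 fold change of 5.82. The list holds NMRK2, LRRC30 and SYNPO2L, which were seen to be high before it was written, so it is no independent evidence of its direction.

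Among the cell type lists fixed in advance, that of peripheral nerve had the highest median. In the Schwann cell and nerve list 6 of its 9 tested genes were higher and 1 lower (7 and 1 when adjusted over the list alone), with a median log2 fold change of 3.09 (camera adjusted p = 2.43e-06). MBP, a myelin protein (ENSBTAG00000022890, chromosome 24, 2224463 to 2328579), measured 19.4 ± 9.35 against 2.28 ± 0.846 CPM (SD, n = 5). Periaxin (PRX) and the adhesion molecule NCAM1 rose by 2.96 ± 0.46 and 3.42 ± 0.58 on the log2 scale (± SE). S100B, a calcium-binding protein also made by adipocytes, went the other way (-1.46, edgeR adjusted p = 0.0167). The list median lay 3.26, 2.44, 1.81, 3.33 and 3.36 above the subcutaneous mean in intramuscular replicates 1 to 5. In the mural cell list (pericytes and vascular smooth muscle) 3 of its 7 tested genes were higher and 0 lower (4 and 1 when adjusted over the list alone), with a median of 0.61 and a camera adjusted p of 0.00934. RGS5 (426 ± 147 against 52.1 ± 14.0 CPM) and CSPG4 (174 ± 30.9 against 75.6 ± 18.3 CPM) are pericyte markers among the higher ones. Of the 7 mural genes 4 had a positive and 3 a negative log2 fold change, so they did not move one way. With an estimated correlation the adjusted p was 0.133 for the nerve list and 0.508 for the mural list. The mural list median had a slope of 0.43 (0.36 to 0.51 with 1 library left out) on the log2 residual muscle level among intramuscular libraries, and the list had an adjusted p of 0.0524 with the residual muscle share as a covariate.

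The macrophage, stromal progenitor and endothelial lists had negative medians in intramuscular fat, with 4 members of each lower past the threshold and the others not. In the macrophage list 0 of its 14 tested genes were higher and 4 lower (0 and 5 when adjusted over the list alone, median log2 fold change -0.91, camera adjusted p = 0.00443). The complement C1q chains C1QA and C1QC, made by tissue macrophages, measured 37.1 ± 7.03 against 121 ± 55.6 CPM and 23.4 ± 6.09 against 90.7 ± 49.9 CPM (SD, n = 5). The macrophage list median stood at 0.41, 0.25, -1.43, -0.33 and 0.91 in subcutaneous replicates 1 to 5 relative to their mean, so replicate 3 lay below all 5 intramuscular libraries (-1.22 to -0.05). In the fibro-adipogenic progenitor list 0 of its 15 tested genes were higher and 4 lower (0 and 5 when adjusted over the list alone, median -0.54, camera adjusted p = 0.00934). CLEC3B, CD248 and CD34 fell by 1.62, 1.79 and 0.86 on the log2 scale. PDGFRA, the receptor most used to sort these cells, measured 94.9 ± 22.1 against 76.7 ± 24.8 CPM (edgeR adjusted p = 0.417). In the endothelial list 0 of its 13 tested genes were higher and 4 lower (0 and 5 when adjusted over the list alone, median -0.42, camera adjusted p = 0.0188). ROBO4, CLDN5 and EGFL7, genes of vessel-lining cells, fell by 1.13, 1.36 and 1.16. The macrophage, progenitor and endothelial list medians were lower in intramuscular fat in 4, 3 and 5 of 5 pairs. With an estimated correlation the adjusted p was 0.508 for each of these 3 lists. For the macrophage, progenitor and endothelial lists it was 0.126, 0.0836 and 0.0836 by fry, and 0.0736, 0.118 and 0.0914 with the residual muscle share as a covariate. Without intramuscular replicates 1 and 3, those with the most residual muscle counts, it was 0.0553, 0.0553 and 0.0720 for the macrophage, progenitor and endothelial lists, and without subcutaneous replicate 1 it was 0.0664 and 0.105 for the latter 2. For the endothelial list it was 0.050, at the threshold, without subcutaneous replicate 2.

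The mature adipocyte and lipid synthesis lists had negative medians in intramuscular fat, and most single members did not pass the gene test. In the mature adipocyte list 1 of its 16 tested genes were higher and 2 lower (1 and 4 when adjusted over the list alone, median log2 fold change -0.71, camera adjusted p = 0.0066, 0.508 with an estimated correlation). The fatty acid carrier FABP4 (ENSBTAG00000037526, chromosome 14, 44676542 to 44681059) fell from 5952 ± 1874 to 2496 ± 743 CPM, and CFD, the secreted protease adipsin, from 127 ± 61.0 to 44.9 ± 14.1 CPM (SD, n = 5). S100A1, which striated muscle also expresses, rose by 4.27 ± 0.58 on the log2 scale, or by 3.40 without intramuscular replicate 1. The adipogenic factor PPARG (-0.77 ± 0.25, ± SE), leptin (LEP, -0.64 ± 0.44), adiponectin (ADIPOQ, 0.20 ± 0.35) and the lipid droplet protein PLIN1 (-0.34 ± 0.31) had edgeR adjusted p of 0.0589, 0.339, 0.742 and 0.477. PPARG had one of 0.0400 without intramuscular replicate 4 and 0.0209 by DESeq2. In the de novo lipogenesis list 0 of its 19 tested genes were higher and 2 lower (0 and 1 when adjusted over the list alone). Of the 19, 17 had a negative fold change (median -0.74, camera adjusted p = 0.00313, 0.508 with an estimated correlation).

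Pyruvate carboxylase (PC, ENSBTAG00000019700, chromosome 29, 44862572 to 44965356) and the pentose phosphate enzyme PGD were the lipogenesis genes past the threshold, at 275 ± 82.0 against 617 ± 150.4 CPM and 425 ± 225 against 964 ± 283 CPM. PGD (edgeR adjusted p = 0.0479) stayed past it only without intramuscular replicate 4 or subcutaneous replicate 1, and was at 0.109 without intramuscular replicate 3 and 0.0615 by limma voom. Fatty acid synthase (FASN), the desaturase SCD and acetyl-CoA carboxylase (ACACA) measured 10379 ± 5535 against 20711 ± 4113 CPM, 18975 ± 8786 against 32499 ± 9385 CPM and 730.5 ± 474 against 1368 ± 196 CPM. Their edgeR adjusted p were 0.0919, 0.187 and 0.148 (0.0211 for FASN by DESeq2). With the animal as a block the edgeR adjusted p were 0.0529, 0.0851 and 0.0527. In intramuscular replicates 1 to 5 the list median was -2.14, -1.07, -0.72, -0.12 and -0.12 relative to the subcutaneous mean. That of the mature adipocyte list was -1.95, -0.74, -0.94, -0.25 and -0.10, beside residual muscle shares of 0.584, 0.153, 0.281, 0.0924 and 0.106%. Both medians were lower in 5 of 5 pairs, with intramuscular minus subcutaneous differences of -1.71, -0.84, -0.66, -0.49 and -0.45 for lipogenesis and -1.96, -0.56, -0.92, -0.08 and -0.47 for adipocyte genes in pairs 1 to 5. With THRSP, which both lists hold, left out, the difference between these medians changed by -0.0426 from subcutaneous to intramuscular fat (SD 0.375 and 0.238, n = 5, two-sided exact permutation p = 0.817, or 0.688 by sign flips of the pairs). By fry the adjusted p of the adipocyte and lipogenesis lists were 0.0836 and 0.103. With the residual muscle share as a covariate they were 0.779, in the opposite direction, and 0.832. The adipocyte list had an adjusted p of 0.0584 without intramuscular replicate 1 and 0.263 without replicates 1 and 3.

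**Figure D2:**
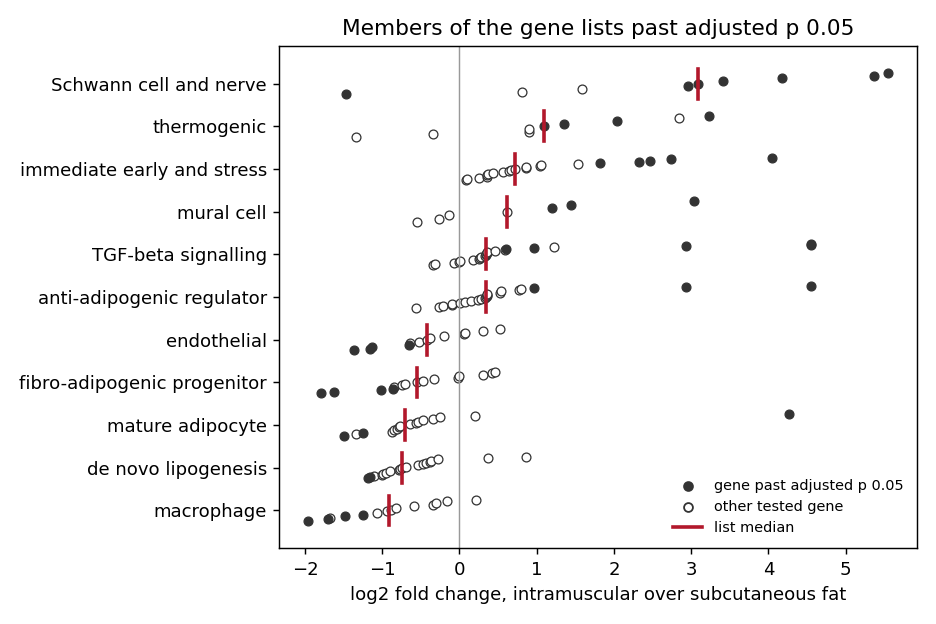
Log2 fold changes (intramuscular over subcutaneous fat, x axis) of the tested members of each gene list fixed in advance with a camera adjusted p under 0.05, one line per list. Filled points are genes past an edgeR adjusted p of 0.05, open points other tested genes, and red bars list medians, from -0.91 for macrophage markers to 3.09 for nerve markers; the lists shown are those fixed in advance, and with an estimated correlation none of them passed.

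Among other lipid genes, the uptake, lipolysis, oxidation and triacylglycerol lists did not pass the list test, and the thermogenic list did. The fatty acid carriers of muscle and fat parted: FABP3, the muscle and heart form, rose (45.8 ± 37.8 against 3.15 ± 1.53 CPM, with an intramuscular mean of 29.7 CPM without replicate 1) with the transporter SLC27A1 (1.23 on the log2 scale), while FABP5 fell by 1.12 beside FABP4. FABP3 and SLC27A1 rose with the log2 residual muscle level among intramuscular libraries, with slopes of 1.18 and 0.69. The fatty acid uptake list had 2 higher and 3 lower of 13, or 2 and 3 adjusted over the list alone. For fatty acid uptake genes the list adjusted p was 0.426, and 0.0336 by fry. Lipolysis genes had 0 higher and 1 lower of 15, or 0 and 1 adjusted over the list alone. For lipolysis genes the list adjusted p was 0.149. Monoglyceride lipase (MGLL) fell by 1.30. Hormone-sensitive lipase (LIPE, -0.88 ± 0.34 ± SE) and adipose triglyceride lipase (PNPLA2, -0.82 ± 0.39) had edgeR adjusted p of 0.106 and 0.179, or 0.0452 and 0.0470 with the animal as a block, and LIPE 0.0452 by DESeq2. Lipoprotein lipase (LPL) measured 1935 ± 979 against 2226 ± 449 CPM (edgeR adjusted p = 0.719). Fatty acid oxidation genes had 0 higher and 3 lower of 18, or 3 and 8 adjusted over the list alone. For fatty acid oxidation genes the list adjusted p was 0.0769, but 0.0480 without intramuscular replicate 4 and 0.0492 without subcutaneous replicate 4. The carnitine enzyme CPT2 had a log2 fold change of -1.02. Triacylglycerol synthesis genes had 0 higher and 1 lower of 14, or 0 and 0 adjusted over the list alone. For triacylglycerol synthesis genes the list adjusted p was 0.0769, but 0.0428 without intramuscular replicate 4 and 0.0349 without subcutaneous replicate 3. In the thermogenic list (brown and beige fat) 4 of its 9 tested genes were higher and 0 lower (6 and 1 when adjusted over the list alone). The median log2 fold change was 1.09, with a camera adjusted p of 0.00424 and one of 0.133 with an estimated correlation. Of the 9 thermogenic genes 7 had a positive and 2 a negative fold change. The lower of these 2 was CIDEA, at -1.34 on the log2 scale and not past the threshold. PRDM16, a transcription factor of brown fat, rose most (17.4 ± 4.47 against 1.85 ± 1.09 CPM), and COX7A1, a respiratory subunit of muscle and brown fat, rose by 1.36. The 4 higher thermogenic genes followed the log2 residual muscle level among intramuscular libraries with a median slope of 0.54, with COX7A1 at 0.72 and PRDM16 at 0.36. UCP1 was not analysed here, nor were CEBPA, DGAT2 and ACTA1.

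The TGF-beta signalling list had a positive median, with INHBA and TGFB3 among its higher genes. In the TGF-beta signalling list 5 of its 22 tested genes were higher and 0 lower (7 and 0 when adjusted over the list alone), with a median log2 fold change of 0.35 and a camera adjusted p of 0.000665. INHBA, the subunit of activin A (ENSBTAG00000048508, chromosome 4, 79288772 to 79302445), measured 33.1 ± 14.3 against 1.41 ± 0.812 CPM and TGFB3 (ENSBTAG00000012004, chromosome 10, 87237844 to 87271480) 151 ± 16.5 against 19.7 ± 10.2 CPM. Their edgeR adjusted p were 7.49e-05 and 8.69e-05. MSTN, the muscle growth inhibitor myostatin, stood at 1.74 ± 2.01 against 0.0645 ± 0.144 CPM (edgeR adjusted p = 0.0212, or 0.0613 without intramuscular replicate 1). Its intramuscular mean was 0.845 CPM without replicate 1, and its subcutaneous mean 0 without replicate 1. In the list of factors that restrain adipocyte differentiation 3 of its 22 tested genes were higher and 0 lower (4 and 0 when adjusted over the list alone, median 0.34, camera adjusted p = 0.00313). All 3 called genes also belong to the TGF-beta list. The matrix glycoprotein TNC (ENSBTAG00000000575, chromosome 8, 104208978 to 104311676) measured 554 ± 127 against 24.5 ± 18.9 CPM, and THBS1, an activator of latent TGF-beta, rose by 1.99 ± 0.43. TNC also belongs to a list of tendon and dense connective tissue genes, chosen after the data were seen, of which 9 of 11 were higher. The proteoglycan BGN rose by 0.70 ± 0.21 (edgeR adjusted p = 0.0485) and passed the threshold without subcutaneous replicate 5 but in no other fit that left out 1 library (up to 0.126, without intramuscular replicate 3). The collagen and matrix list as a whole had 3 higher and 0 lower of 22, or 3 and 1 adjusted over the list alone. For collagen and matrix genes the list adjusted p was 0.84. Its median of -0.22 and its mean of 0.13 had opposite signs. The TGF-beta and anti-adipogenic list medians were lower in intramuscular fat in 1 of 5 pairs, pair 1 (by -0.16 and -0.20). With an estimated correlation the adjusted p was 0.508 for the TGF-beta and the anti-adipogenic list.

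**Figure D3:**
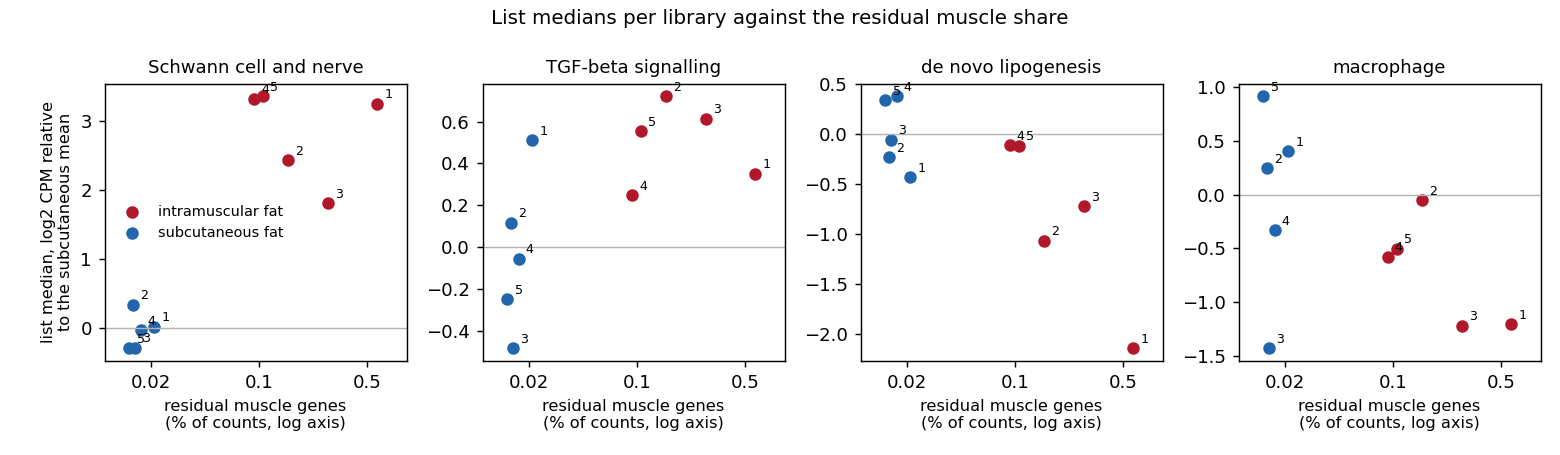
Median of 4 gene lists in each library (y axis, log2 CPM relative to the mean of the subcutaneous libraries) against the percent of counts from the residual muscle list (x axis, log scale). Red points are intramuscular and blue points subcutaneous libraries with their replicate numbers; the lipogenesis median lies at -2.14 in the intramuscular library with the largest share (0.584%) and at -0.12 in both libraries with the smallest, below the subcutaneous library of the same number in 5 of 5 pairs.

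In the immediate early and stress list 5 of its 21 tested genes were higher and 0 lower (7 and 0 when adjusted over the list alone). All 21 had a positive fold change (median 0.72, camera adjusted p = 0.000665, 0.508 with an estimated correlation and 0.0836 by fry). NR4A2, an inducible nuclear receptor, rose by 2.47 ± 0.45 (± SE). In intramuscular replicates 1 to 5 the list median was -0.17, 1.17, 0.40, 1.14 and 2.04 relative to the subcutaneous mean, and 0.32, -0.17, -0.88, 0.37 and 0.65 in subcutaneous replicates 1 to 5.

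Patterning and signalling genes differed one by one. LBX1, a homeobox gene of migrating limb muscle precursors, had no count in subcutaneous fat and was at least 149-fold higher (92.0-fold without intramuscular replicate 1), and HOXA3 rose by 1.34, whereas EN1 and IRX5 had log2 fold changes of -1.70 and -2.87. The homeobox and T-box list had 4 higher and 2 lower of 32, or 5 and 2 adjusted over the list alone. For homeobox and T-box genes the list adjusted p was 0.365. WNT genes had 2 higher and 1 lower of 30, or 2 and 0 adjusted over the list alone. For WNT signalling genes the list adjusted p was 0.0745, but 0.0490 without intramuscular replicate 4 and 0.0190 without subcutaneous replicate 1. Among secreted WNT antagonists, FRZB (15.5 ± 16.3 against 0.353 ± 0.469 CPM) and DKK3 (131 ± 28.8 against 15.8 ± 11.5 CPM) rose and SFRP2 fell by 1.32. The means of FRZB were 8.49 CPM without intramuscular replicate 1 and 0.147 CPM without subcutaneous replicate 4. SFRP2 (edgeR adjusted p = 0.0465) did not pass without intramuscular replicate 1, 2, 3 or 4 or subcutaneous replicate 3 or 5 (adjusted p from 0.0740 to 0.112), nor by limma voom (0.166). GRB14, an inhibitor of the insulin receptor, rose by 4.12 ± 0.76, and the glycolytic enzyme PKM by 2.99 ± 0.48. GRB14 measured 3.88 against 0.221 CPM, with 16 counts over all subcutaneous libraries. PKM followed the log2 residual muscle level among intramuscular libraries with a slope of 1.19 and rose by 2.25 without intramuscular replicate 1. The slopes on that level were 1.46 for FRZB and 1.54 for LBX1, but 0.32 for DKK3 and 0.060 for GRB14. Insulin signalling genes had 1 higher and 0 lower of 17, or 7 and 1 adjusted over the list alone. For insulin signalling genes the list adjusted p was 0.069, but 0.0329 without intramuscular replicate 1 and 0.0253 without subcutaneous replicate 4. It was 0.00499 with the residual muscle share as a covariate and 0.0327 without intramuscular replicates 1 and 3. Glycolysis genes had 1 higher and 3 lower of 13, or 3 and 5 adjusted over the list alone. For glycolysis genes the list adjusted p was 0.426. ALDH1A2, which makes retinoic acid, rose by 3.20 (4.03 without subcutaneous replicate 1) and CYP26B1, which degrades it, fell by 1.73. Retinoic acid genes had 1 higher and 2 lower of 13, or 2 and 5 adjusted over the list alone. For retinoic acid genes the list adjusted p was 0.149. The adipokine list had 0 higher and 3 lower of 18, or 0 and 3 adjusted over the list alone. For adipokine genes the list adjusted p was 0.0539, but 0.0107 without intramuscular replicate 2, 0.0490 without intramuscular replicate 4, 0.0395 without intramuscular replicate 5, 0.0180 without subcutaneous replicate 3 and 0.0162 without subcutaneous replicate 5. It passed with the animal as a block (adjusted p = 0.0276).

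The other lists showed the following counts. T and NK cell markers had 1 higher and 0 lower of 11, or 1 and 0 adjusted over the list alone. For T and NK cell genes the list adjusted p was 0.968. Their median was -0.21 and their mean 0.098, and the T cell kinase ZAP70 had a log2 fold change of 1.74. Mast cell and granulocyte markers had 0 higher and 2 lower of 7, or 0 and 2 adjusted over the list alone. For mast cell genes the list adjusted p was 0.0769, but 0.0320 without intramuscular replicate 2 and 0.0292 without subcutaneous replicate 3. The mast cell receptor KIT had a log2 fold change of -1.13. Interferon response genes had 0 higher and 2 lower of 16, or 0 and 3 adjusted over the list alone. For interferon response genes the list adjusted p was 0.0539, but 0.0320 without intramuscular replicate 2, 0.0478 without intramuscular replicate 5, 0.00615 without subcutaneous replicate 4 and 0.0406 without subcutaneous replicate 5. With the stricter filter it was 0.0372. The interferon regulator IRF7 had a log2 fold change of -1.33. Pro-adipogenic regulators had 0 higher and 1 lower of 20, or 0 and 0 adjusted over the list alone. For pro-adipogenic regulator genes the list adjusted p was 0.0866, but 0.0480 without intramuscular replicate 4 and 0.0349 without subcutaneous replicate 3. Nuclear genes of oxidative phosphorylation had 0 higher and 1 lower of 26, or 0 and 1 adjusted over the list alone. For these genes the list adjusted p was 0.0776, but 0.0204 without intramuscular replicate 1 and 0.00647 without subcutaneous replicate 1. Steroid and glucocorticoid genes had 1 higher and 0 lower of 13, or 1 and 0 adjusted over the list alone. For steroid and glucocorticoid genes the list adjusted p was 0.682. Cell cycle genes had 1 higher and 0 lower of 18, or 1 and 0 adjusted over the list alone. For cell cycle genes the list adjusted p was 0.84. The cyclin CCNA2 rose by 1.59 (edgeR adjusted p = 0.0221, or 0.0541 and 0.0728 without intramuscular replicates 1 and 3). Cytokines and chemokines had 0 higher and 2 lower of 16, or 0 and 2 adjusted over the list alone. For cytokine and chemokine genes the list adjusted p was 0.84. Antigen presentation genes had 0 higher and 0 lower of 7, or 0 and 0 adjusted over the list alone. For MHC class II and antigen presentation genes the list adjusted p was 0.386. The median and the mean had opposite signs in the fatty acid uptake (mean 0.0068), glycolysis (0.013), cell cycle (0.14) and cytokine (0.24) lists as well. For 4 lists too few genes were tested for a list test. Satellite cell markers had 0 of 3 tested genes past the threshold, B and plasma cell markers 1 lower of 3, erythrocyte markers 0 of 2 and skin epithelium markers 1 higher and 1 lower of 2. The keratin KRT10 was the lower skin gene (-1.15, edgeR adjusted p = 0.0382, or 0.0758 with the animal as a block). It passed without subcutaneous replicate 1 or 4 but not without any other library (adjusted p from 0.0557 to 0.0977). Adjusted over the list alone these counts were 0, 2 lower, 0, and 1 higher and 1 lower.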

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

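All tests of explanations in this part were chosen after the result they bear on was seen, and their bounds after slopes on the residual muscle level had been looked at in several forms. Of 254 groups of 5 values examined, 14 had 1 library far from the rest (its gap to the nearest other, over the whole range, above 0.710), and chance marks about 1 group in 20. Intramuscular replicate 1, with the largest residual muscle share, was the lowest library for the medians of the fatty acid uptake list (-0.99, others -0.29 to -0.19) and the cytokine list (-0.49, others 0.12 to 0.21), and for log2 CPM of PPARG (6.47, others from 7.63), PLIN1 (9.70, others from 11.13) and PC (7.09, others from 8.10). It was the highest for MSTN (2.45, others at most 0.30). INHBA was highest in intramuscular replicate 2 (5.87, others at most 4.94), and CHST9 in replicate 4 (-0.71), the only intramuscular library with a count of it. In subcutaneous fat, replicate 3 was lowest for the complement list median (-1.38, others from 0.12) and C3 (4.71, others from 7.05), and replicate 4 for RGS5 (4.84, others from 5.66). GADL1 in replicate 4 (-1.42) and MSTN in replicate 1 (-1.12) were the only subcutaneous libraries with a count of that gene, and the residual muscle median stood at 0.049 in replicate 5 and at 0 in the others.

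Chance in the grouping of the libraries was an unlikely source of the number of genes called. The depots gave 1533 calls and the highest of the other splits drawn gave 1, so 1 of 100 splits, the real one, gave as many. The 8 other drawn splits that also part all 5 pairs gave 0, too few splits to exclude chance when the libraries are taken as pairs.

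The 845 genes higher in intramuscular fat were set against muscle fibre RNA, which would make a gene's log2 CPM follow the residual muscle level among the 5 intramuscular libraries, with a slope set by its excess. The median ratio of observed to needed slope was 0.50 over the 828 higher genes outside the muscle list, from 0.47 to 0.63 when each intramuscular library was left out, against 1.29 for the higher genes of the muscle list itself, 0.80 (0.68 to 0.94) for the 169 of the 828 that were at least 8-fold higher, 0.47 (0.44 to 0.56) for the other 659 and 0.79 (0.66 to 0.84) for the 4 higher thermogenic genes. For the group as a whole, muscle fibre RNA and a depot difference cannot be told apart because the ratio lies on both sides of the bound of 0.5, although the ratio lay above it for the genes at least 8-fold higher. The tables argue against muscle fibre RNA as the whole source for the 6 higher nerve genes (ratio -0.39, or -1.72 to -0.17 with a library left out) and the 5 higher TGF-beta genes (0.060, or -0.016 to 0.335), although MSTN on its own had a ratio of 1.21 and NCAM1 one of 0.996. Nerve within the muscle and a difference between the depots' own cells stay open for these.

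The fall of the de novo lipogenesis list was set against dilution by muscle fibre RNA and against a lower share of adipocytes. Its median log2 fold change went from -0.74 to -0.43 without the 2 libraries with the most residual muscle counts, and its slope on the residual muscle level among intramuscular libraries was -0.86 (-0.93 to -0.58 with 1 library left out), with a ratio of observed to needed slope of 1.17 (0.93 to 1.28) over the 17 genes with a negative fold change and 0.58 (0.46 to 0.61) over the 2 past the threshold. The first value keeps more than 50% of the change, which met the bound stated against dilution and was at first read as excluding it. That reading was changed after the result, because the 3 libraries left still held 0.0924 to 0.153% residual muscle counts against 0.0167% in subcutaneous fat, so dilution and lower lipogenesis in the depot cannot be told apart. A lower share of adipocytes as the only change would raise the markers of other cell types alike. The nerve and macrophage list medians moved apart by 3.56 in the same direction in 5 of 5 pairs (exact permutation p = 0.00794, or 0.0625 by sign flips of the pairs, each the smallest possible). The SD of this difference between libraries was 0.784 in intramuscular and 0.868 in subcutaneous fat. Medians that part this far go against a lower share as the only difference between the depots. The 2 lists had already been seen to move in opposite directions, so these p-values and the count of pairs are no independent evidence. Neither list holds a lipogenesis gene. The lipogenesis median fell about as far as the mature adipocyte median (difference -0.0426, exact permutation p = 0.817). A lower share of adipocytes therefore stays open for the fall of the lipogenesis list.

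The complement list, chosen after the data were seen, had a negative median that passed by camera but not with an estimated correlation (adjusted p = 0.268), and dilution by muscle fibre RNA was weighed for it in the same way. Its median log2 fold change went from -0.56 to -0.38 without the 2 libraries with the most residual muscle counts, and its slope on the residual muscle level was -0.37 (-0.47 to -0.21). The bound stated against dilution was met here too, and the same change of reading was made, so for the list as a whole dilution and a depot difference cannot be told apart. For its 5 lower genes the ratio of observed to needed slope was 0.10 (-0.02 to 0.18), which argues against dilution as the whole cause of their fall, and it was 0.31 (0.13 to 0.38) over the 14 genes with a negative fold change, whereas the list median did fall with the muscle level. Subcutaneous replicate 3 lay at -1.38, below all 5 intramuscular libraries. The macrophage list median was also lowest in that library (-1.43). Both medians were lower in intramuscular fat in 4 of 5 pairs, all but pair 3, and whether macrophages account for the complement fall was not tested.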

How the results depend on the processing

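The alternatives that use the residual muscle list or share, and the share itself, were chosen after the data were seen, and the others before. Over the alternatives that left out 1 library, the genes higher in intramuscular fat numbered 494 to 1008 and the lower ones 263 to 887, those of at least 2-fold 439 to 721 and 151 to 348, and the gene lists 6 to 7 higher and 4 to 10 lower. The mean of the log2 residual muscle share differed between depots by 3.11 to 3.78. With the animal as a block it differed by 3.52, where the sign-flip p of 0.0625 is the smallest that 5 pairs allow. Of the 160 genes the naming rule covers, 102 were called and 68 of these kept the call with each library left out in turn, while 21 others gained one in some fit. The genes in the text were chosen with this seen and are steadier (65 of 72). RLE scaling, no filter and the stricter filter kept 101, 102 and 100 of the 102, DESeq2 all 102 and limma voom 96; of the genes in the text, limma voom lost PGD, SFRP2 and TNMD. The interferon list passed with the stricter filter (0.0372).

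DESeq2 called 1369 genes higher and 1171 lower, and the cause was not tested. With the residual muscle share as a covariate 236 genes were higher and 46 lower (228 and 35 by at least 2-fold), and with the block added 214 and 44 (214 and 44), where fewer residual degrees of freedom and the overlap of share and depot leave less to test. Whether calls were lost to this or to the removal of an effect that follows the share was not tested. Without the 2 libraries with the most residual muscle counts the numbers were 306 and 67 (289 and 51), with fewer samples. Of the 102 named calls these alternatives kept 38, 23 and 46. With an estimated correlation 0 of the 31 lists fixed in advance were higher and 0 lower. Of the 5 lists lower by camera, none passed by fry (adjusted p from 0.0836 to 0.126), with the covariate (from 0.0736 to 0.832) or with block and covariate (from 0.130 to 0.848). Without the 2 libraries only lipogenesis did (0.0327). The 1, 1, 2 and 2 lists lower under these 4 alternatives were fatty acid uptake by fry (0.0336), oxidative phosphorylation with the covariate (0.00149), that list (1.73e-07) and the mast cell list (0.0399) with block and covariate, and lipogenesis and oxidative phosphorylation (0.0223) without the 2 libraries. Of the 6 higher lists, immediate early and stress was lost by fry (0.0836), the mural list with the covariate (0.0524) and the thermogenic list with block and covariate (0.0626). Insulin signalling was gained with the covariate (0.00499), block and covariate (0.0216) and without the 2 libraries (0.0327), and WNT signalling with block and covariate (0.0137).

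Some genes and lists named in the text changed sign, none of them past the threshold after it. LEP went to 0.33 with the covariate and 0.19 with block and covariate, and PLIN1 to 0.30 and 0.65. LPL went to 0.50 and 0.44, to 0.12 without the 2 libraries, and lay between -0.43 and 0.0063 with 1 library left out (positive without intramuscular replicate 1). The list adjusted p after a change of direction, with the covariate and then with block and covariate, were 0.779 and 0.752 for mature adipocyte, 0.779 and 0.666 for lipolysis, 0.980 and 0.752 for homeobox and T-box, 0.798 and 0.569 for cell cycle, and 0.579 and 0.666 for cytokine genes. Without the 2 libraries cell cycle stood at 0.924 and cytokine genes at 0.728. Cytokine genes also changed direction with no filter (0.975) and T and NK cell genes with the stricter filter (0.804). With 1 library left out, the lists that changed direction in some fit had an adjusted p of 0.796 to 0.992 (T and NK cell), 0.657 to 0.991 (cell cycle), 0.50 to 0.981 (cytokine) and 0.448 to 0.967 (collagen). For all of these the cause was not tested. With the animal as a block 1013 genes were higher and 871 lower, 1385 of them among the 1533. LIPE, PNPLA2 and the adipokine list then passed the threshold and KRT10 (0.0758) no longer did. The residual muscle share could not pass it by pairs, since 0.0625 is the smallest sign-flip p of 5 pairs. The block changed no other call of a gene or list named in the text, and kept 99 of the 102. Settings that needed the myofibre list were not run, since none of its genes had values.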

Other observations

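The tests and the gene choices in this part were made after the data were seen. Tendon and dense connective tissue genes formed a further group above subcutaneous fat: of 11 tested genes 9 were higher and 0 lower, with a median log2 fold change of 3.35 (camera adjusted p = 8.96e-15, or 0.00988 with an estimated correlation). The list median had a slope of 0.86 (0.78 to 1.38 with 1 library left out) on the residual muscle level among intramuscular libraries. The ratio of observed to needed slope was 0.64 (0.61 to 1.11) for the 9 higher genes, and at least 0.5 for 8 of them. TNMD, a marker of tendon cells, measured 27.3 ± 23.0 against 0.202 ± 0.349 CPM (SD, n = 5), the matrix protein THBS4 643 ± 366 against 63.2 ± 86.3 CPM and the collagen-binding proteoglycan FMOD 396 ± 118 against 103 ± 34.95 CPM. Without 1 subcutaneous library the subcutaneous means were 0.0510 CPM for TNMD (replicate 2) and 24.8 CPM for THBS4 (replicate 1). TNMD had an adjusted p of 0.0577 by limma voom and 0.0006 by edgeR. Among complement genes, 0 of 18 were higher and 5 lower (median -0.56, camera adjusted p = 0.00621, 0.268 with an estimated correlation and 0.0765 by fry), with C2 at 21.6 ± 15.2 against 104 ± 48.7 CPM, C3 at 32.8 ± 14.4 against 124 ± 56.2 CPM and the lectin pathway protease MASP1 at 43.4 ± 13.3 against 138 ± 55.1 CPM. Of 10 pentose phosphate genes, which supply NADPH, 3 were lower and 0 higher (median -0.49, camera adjusted p = 0.018, 0.246 with an estimated correlation). That list had an adjusted p of 0.362 with the residual muscle share as a covariate, 0.0788 with block and covariate and 0.0621 without the 2 libraries with the most residual muscle counts, and the complement list 0.119 and 0.296 with the covariate without and with the block. None of these lists was fixed in advance, so their p-values are no independent evidence of their direction. They were adjusted over the 4 added lists alone and cannot be set beside those of the 31.

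The gene without a symbol ENSBTAG00000052709 (chromosome 2, 18333414 to 18335770 in the deposited table) measured 2477 ± 2489 against 0.243 ± 0.279 CPM (edgeR adjusted p = 2.27e-05), and 6708, 1562, 2631, 721 and 765 CPM in intramuscular replicates 1 to 5 (mean 1419.9 without replicate 1). A hypothesis is that its counts come from the TTN locus, the gene of the giant muscle protein titin. In the deposited table it lies between CCDC141 and PLEKHA3, and in the ARS-UCD2.0 gene table TTN and LOC112442545 lie between them, so the position does not single out TTN. Its slope on the residual muscle level among intramuscular libraries was 1.496 (1.4 to 1.6 with 1 library left out), which is consistent with a muscle fibre source, while no sequence was compared.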
